A study of Drosophila melanogaster with 6 samples.

How the data were processed

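RNA from fly heads was measured on 6 GeneChip Drosophila Gene 1.0 ST arrays, 3 of control flies and 3 of a pool of 7 lines. Per the labels' protocols, total RNA was taken from 15 to 25 heads per genotype, its integrity was checked, and RNA of the seizure lines was mixed in equal amounts before hybridisation. Per the submitters' processing notes the arrays were processed with Affymetrix Expression Console; its version, its algorithm and the genome build are not given in the sources used here. The deposited values are 1 number per array row and array on a log2 scale, which was inferred from their range (3.20 to 14.02) and their medians near 5.6. They were used as deposited, without further scaling. Whatever background correction and normalization the authors applied is therefore part of each value, and a shift common to most genes would have been removed by a normalization between arrays. Array data carry no read depth; the median standard error of a log2 fold change was 0.0677, and the smallest called change was 0.23 in absolute log2.

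Rows were named through a table of the platform's annotation, updated where a row's identifier matched the RefSeq gene table of the fly's Release 6 plus ISO1 MT assembly. Of 16322 rows, 13441 had 1 gene symbol, 555 had several and 2326 had none; 144 symbols were updated. Rows with several symbols were tested but not named. No row was marked as an array control. The named rows stood for 13346 genes, 76 of which had more than 1 row; in list tests such a gene was taken from its row of highest mean. No gene named by the rule below had more than 1 row. No coordinates are given, because the build of the values is not known.

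Groups were taken from the labels. Pool and control were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the log2 values, pool minus control, two-sided, over all rows and with no filter on dim rows. The Benjamini-Hochberg adjusted p had to be under 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 3.78. Fold changes are 2 to the power of the log2 difference. Errors beside group means are SDs over 3 arrays. A total of 37 gene lists of at least 5 measured members, written before the data were examined, were tested with camera at the preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the 37 lists. The counts of members that passed are given over all rows and adjusted over the list alone. Camera compares a list with the other genes, while fry asks whether a list's genes move one way on balance. With an estimated correlation camera uses only the 4 residual degrees of freedom, so a list can fail it for that reason alone. Lists share some members.

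The genes named were fixed by a rule. They were the 7 genes named for the pooled lines, the 12 largest rises and 12 largest falls among called rows with 1 symbol whose groups did not overlap, and in each list up to 4 called members of largest change or, where none was called, up to 2 of smallest p. The alternatives were quantile normalization, centring each array on its median, dropping the dimmest 25% of rows, testing only rows with 1 symbol, the replicate number as a block, leaving out each array, eBayes with a trend and robust settings, array weights, an ordinary t-test, other fold minimums, the mean over a gene's rows, and the other list tests. Some were added after seeing the data: the muscle and cuticle lists without their largest risers, and all calls without the cuticle, muscle and digestive lists.

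The limma steps were tested on simulated arrays with the 16322 real row means and 200 changed rows. They recovered 20% of rows changed by 0.3 log2, 88% of those changed by 0.585, 94% at 1 and 100% at 2, with 10 false calls (6.21% of calls). With no change 0 of 37 lists were called, and a ribosomal list shifted by 0.2 was called. The simulated rows varied independently of each other. The simulation therefore cannot show how often lists of correlated genes are called falsely. In the real data the estimated correlation of the mitochondrial list was 0.84. No array duplicated another: the SD of the difference between 2 arrays of a group was 0.150 to 0.180 log2. The first principal component, with 42.9% of the variance, separated the groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.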

Results

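The experiment asked which transcripts change in common in the heads of flies whose bang-sensitive seizures come from altered glia. Bang-sensitive flies seize after a mechanical shock. RNA was hybridised to 6 Drosophila Gene 1.0 ST arrays, 3 labelled control and 3 labelled pool. Controls carried repo-GAL4, a driver active in nearly all glia, together with an empty RNA interference vector. The pool was an equal mixture of RNA from 7 lines crossed to the same driver, 5 with RNA interference against sesB, COX7A, comt, nrv2 or Atpalpha and 2 that overexpress Dube3a or a huntingtin transgene labelled htt.12Q.FL. Each genotype contributed 15 to 25 heads of flies about 3 to 5 days old raised at 25 °C; the labels call the tissue brain, but the protocol took whole heads. Array medians lay between 5.53 and 5.63 on the log2 scale. Correlations across rows were 0.9967 to 0.9978 within groups and 0.9952 to 0.9960 between groups. The number of arrays limits the precision. Nothing in the labels says that the 3 arrays of a group came from separate cultures or separate RNA pools, so all p-values measure the spread between these arrays, which may be technical.

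The largest rises in the pool included cuticle, flight muscle and cytochrome P450 genes, and the largest falls included an odorant-binding protein gene, a neuropeptide gene and another cytochrome P450 gene. The long non-coding RNA lncRNA:CR43264 rose 15.9-fold, from 4.15 ± 0.08 to 8.14 ± 0.13 log2 units (SD, n = 3 per group). Cyp6a2, a cytochrome P450 of insecticide metabolism, rose 5.79-fold, Acp1, an adult cuticle protein, 4.98-fold and Act88F, the indirect flight muscle actin, 3.89-fold. CG9377 fell by 2.05 on the log2 scale, the largest called fall of a named gene, from 9.27 ± 0.05 to 7.22 ± 0.12 (SD, n = 3 per group). In total 473 of 16322 rows (2.90%) passed an adjusted p of 0.05 in limma, 270 higher and 203 lower in the pool. Of these, 125 changed by at least 1.5-fold (84 higher, 41 lower) and 34 by at least 2-fold (28 higher, 6 lower). The called rows with 1 gene symbol stood for 377 genes. In all 473 rows the 3 pool values lay entirely to one side of the 3 control values. The same held for 3504 of all rows, or 21.5%, where chance gives 10%. With each array centred on its median the calls split into 219 higher and 249 lower, against 270 and 203 as deposited. Leaving out control replicate 1, 2 or 3 gave 283, 246 or 312 called rows, and leaving out pool replicate 1, 2 or 3 gave 231, 232 or 218.

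**Figure D1:**
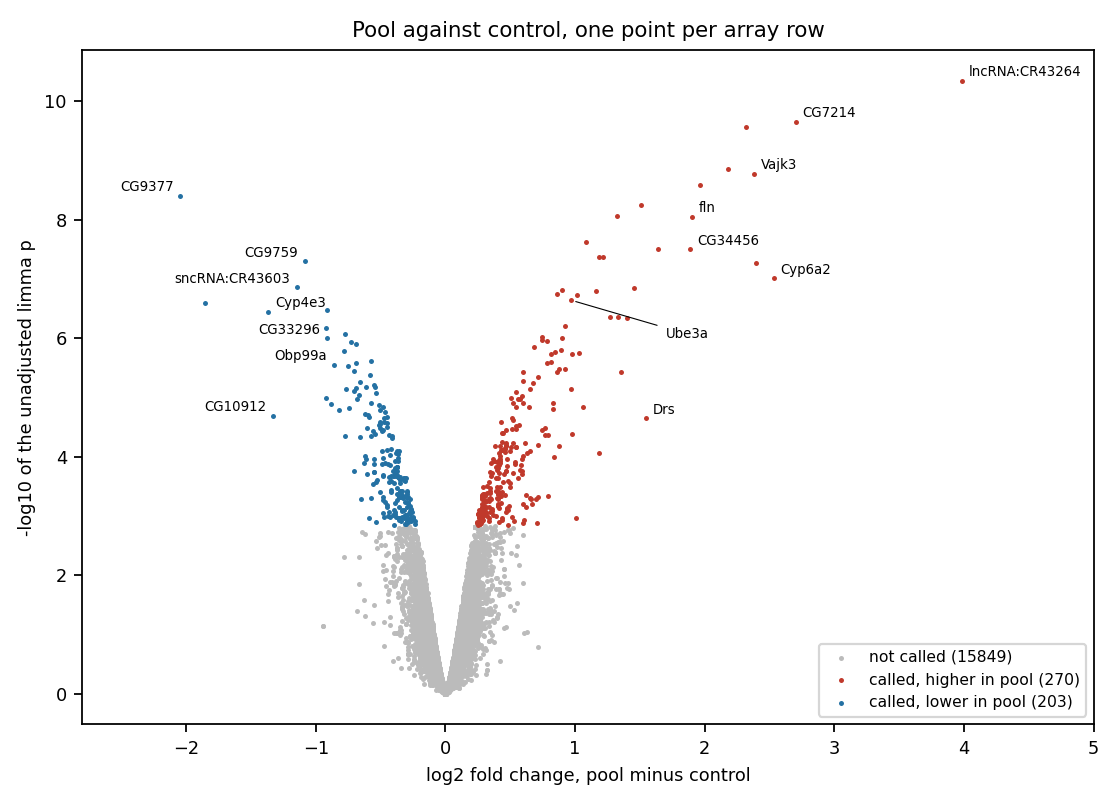
Log2 fold change of the pool over the control (x axis) against -log10 of the unadjusted limma p (y axis), 1 point per array row, with the 270 rows called higher in red, the 203 called lower in blue and the rest in grey. Some of the named genes are labelled, from CG9377 at -2.05 to lncRNA:CR43264 at 3.99.

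Of the 7 genes named for the pooled lines, 5 were measured, and Ube3a was the 1 that changed. One of the 5 is the fly gene htt, and the label of the huntingtin transgene does not say that this gene itself is altered. Ube3a, the fly ubiquitin ligase gene Dube3a that 1 line overexpresses, rose from 8.29 ± 0.08 to 9.26 ± 0.04 (SD, n = 3 per group), a log2 fold change of 0.97 with a standard error of 0.058, or 1.96-fold (limma adjusted p = 0.00015). The control arrays read 8.20, 8.33 and 8.33 and the pool arrays 9.23, 9.30 and 9.25. The RNA interference targets did not pass the test. The adenine nucleotide translocase gene sesB read 11.82 ± 0.06 in the control and 11.88 ± 0.02 in the pool (adjusted p = 0.713), the cytochrome oxidase subunit gene COX7A 8.81 ± 0.09 and 8.87 ± 0.07 (adjusted p = 0.786), and the sodium pump beta subunit gene nrv2 10.75 ± 0.04 and 10.68 ± 0.01 (adjusted p = 0.592). The fly huntingtin gene htt read 6.31 ± 0.10 and 6.30 ± 0.03 (adjusted p = 0.959); whether this row reads the transgene is not given in the sources used here. Each knockdown acts in glia only and in 1 of 7 pooled lines, so these values do not test its strength. Atpalpha and comt are not named in the annotation used here. As a list, the 5 measured genes did not pass the camera test (adjusted p = 0.235) but passed fry (adjusted p = 0.00698). Of them 1 rose and 0 fell over all rows, and the same adjusted over the list alone. The 1 that rose is the overexpressed Ube3a, so the fry result is no separate evidence of a shared shift.

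**Figure D2:**
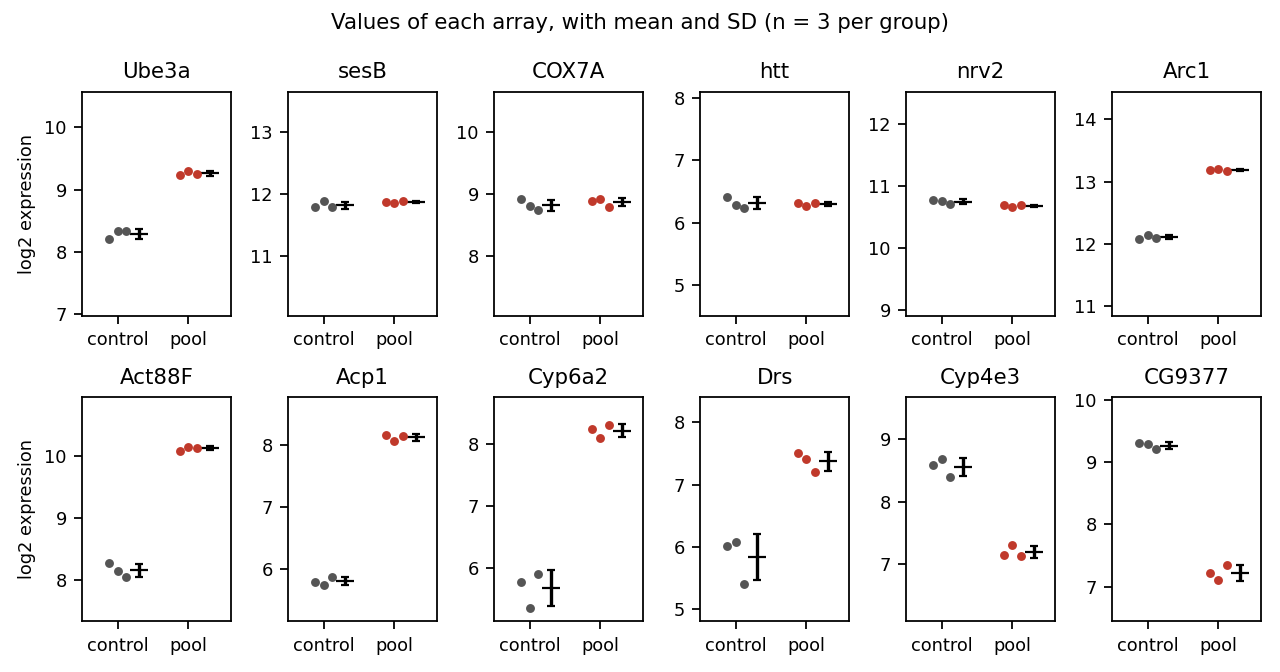
Log2 expression (y axis) of 12 genes on each of the 3 control arrays (grey) and 3 pool arrays (red), with the group mean and SD in black; each panel spans the same height. Ube3a moves from a mean of 8.29 to 9.26, while sesB, COX7A, htt and nrv2 differ by at most 0.07.

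The 12 largest rises also included CG7214 (6.52-fold), CG8736 (5.27-fold), Vajk3 (5.22-fold), Cyp4p2 (4.52-fold), fln (3.74-fold), CG34456 (3.70-fold), Cpr100A (3.11-fold) and Drs (2.92-fold). Vajk3 belongs to a family of secreted proteins, Cpr100A carries a chitin-binding cuticle domain, fln encodes the flight muscle protein flightin, and Drs encodes the antifungal peptide drosomycin. Adjusted p was 1.48e-06 for CG7214, 5.15e-05 for CG8736, 3.95e-05 for CG34456 and 7.41e-07 for lncRNA:CR43264. Drs was the most variable of these, at 5.83 ± 0.37 in the control and 7.38 ± 0.15 in the pool (adjusted p = 0.00349, SD, n = 3 per group). After CG9377 (adjusted p = 9.22e-06), the largest falls were in Cyp4e3, which fell by 1.37 on the log2 scale (adjusted p = 0.000208), CG10912, which fell by 1.33 (adjusted p = 0.00331), and the small non-coding RNA sncRNA:CR43603, which fell by 1.15 (adjusted p = 0.000115). CG9759 stood at -1.09 and CNMa, which encodes the neuropeptide CNMamide, at -0.92. CG33296 and phu both stood at -0.91, the serpin gene Spn47C at -0.88, the odorant-binding protein gene Obp99a at -0.86, and the N-acetylglucosamine kinase gene Nagk and the folate enzyme gene CG8665 at -0.78. Adjusted p was 5.15e-05 for CG9759, 0.000328 for CNMa, 0.000442 for CG33296, 0.000199 for phu, 0.00239 for Spn47C, 0.000861 for Obp99a, 0.000605 for Nagk and 0.000404 for CG8665. All 24 kept their call with any 1 array left out.

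Single cuticle and muscle genes rose in the pool, at 7 of 47 and 6 of 22 measured, and camera called both lists upward, but neither list passed with an estimated correlation. The estimates were -0.019 for cuticle and 0.0057 for muscle, both below the preset 0.01. A higher correlation among members is therefore not why these 2 calls ended. With an estimated correlation camera draws p from the 4 residual degrees of freedom, far fewer than with the preset. Not passing it is therefore no measure of correlation alone, here or for the lists below. Of 47 measured cuticle genes 7 rose and 0 fell over all rows (12 and 2 adjusted over the list alone), led by Acp1 (log2 fold change 2.32, adjusted p = 1.48e-06), Cpr100A (1.64, 3.95e-05), Cpr97Eb (1.35, 0.00103) and Cpr62Bc (1.22, 4.68e-05). In the cuticle list 29 genes were higher and 18 lower. Its median was 0.06 and its shift passed camera (adjusted p = 0.000523), with adjusted p = 0.160 with an estimated correlation. Without those 4 genes, an alternative added after seeing the data, the shift no longer passed (mean 0.08, adjusted p = 0.113). Of 22 muscle genes 6 rose and 0 fell (11 and 2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 2.85e-07; adjusted p = 0.143 with an estimated correlation). Act88F stood at 1.96 (adjusted p = 7.01e-06), fln at 1.90 (1.45e-05) and the flight muscle troponin C gene TpnC4 at 1.16 (0.000118). TpnC73F stood at 0.37 (0.0382), a call that was lost with any 1 array left out (adjusted p up to 0.122) and with each array centred on its median (0.0548). Of 42 digestive enzyme genes 5 rose and 0 fell (7 and 2 adjusted over the list alone), with a median of 0.02 and no list shift (camera adjusted p = 0.771). They included the trypsin gene epsilonTry (0.68, adjusted p = 0.00145), Jon99Ci (0.62, 0.0235), the lysozyme gene LysP (0.57, 0.0042) and Mal-A6 (0.41, 0.0322). The calls of Jon99Ci and Mal-A6 were lost on leaving out any 1 array but pool replicate 3 (adjusted p up to 0.0941 and 0.115). Of 18 fat body genes 2 rose and 1 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.527). The storage hexamerin gene Lsp2 rose 2.51-fold (adjusted p = 1.45e-05) and Obp99b stood at 0.55 (0.00428), while Obp99a was the 1 that fell. That list's median (-0.08), mean (-0.01) and camera direction were downward, while fry's was upward.

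Detoxification genes moved in both directions as single genes, and camera called no list of them. Camera looks for a shift in one direction, so it cannot detect a list whose members move both ways. A mixed form of fry that ignores direction passed the P450 (adjusted p = 4.83e-06), glutathione S-transferase (3.84e-06), UDP-glycosyltransferase (4.83e-06) and antioxidant (0.000105) lists. It also passed lists with 0 called members, such as the neuronal and synaptic list (0.0079), so it does not set these lists apart. Of all 13346 genes 377 were called. Of 76 cytochrome P450 genes 8 rose and 7 fell (11 and 11 adjusted over the list alone), and the list did not shift (median -0.00, mean 0.05, camera adjusted p = 0.888). Cyp6a2 stood at 2.53 (adjusted p = 8.93e-05), Cyp4p2 at 2.18 (5.49e-06) and Cyp6a9 at 0.86 (0.000125), against Cyp4e3 at -1.37. Of 37 glutathione S-transferase genes 4 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.592), and the list's median (-0.02) and mean (0.09) differed in sign. The 4 risers were GstD5 (1.18, adjusted p = 0.00857), GstE7 (0.84, 0.0097), GstS1 (0.79, 0.000473) and GstD2 (0.71, 0.00121). Of 26 UDP-glycosyltransferase genes 3 rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.592). Among them were Ugt36E1 at 0.53 (0.0435), Ugt301D1 at 0.42 (0.00936), Ugt35B1 at -0.38 (0.00854) and Ugt37D1 at -0.35 (0.0181). The call of Ugt36E1 was lost on leaving out any 1 array but pool replicate 2 (adjusted p up to 0.145). That of Ugt37D1 was lost with any but pool replicate 1 (up to 0.0719). Of 19 antioxidant genes 1 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.616). Nmdmc, a mitochondrial folate enzyme gene, rose 1.86-fold (adjusted p = 0.000605), and Sod3, the extracellular superoxide dismutase gene, fell by 0.67 on the log2 scale (0.00198). The methionine sulfoxide reductase gene MsrA stood at -0.48 (0.0244), a call that was lost on leaving out any 1 array but control replicate 3 (adjusted p up to 0.0923).

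Injury genes shifted upward as a list, while antimicrobial peptide genes went both ways. Of 15 injury and JNK genes 3 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 1.33e-05; adjusted p = 0.248 with an estimated correlation). Gadd45, a stress-response gene, stood at 0.55 (adjusted p = 0.0075), the ETS transcription factor gene Ets21C at 0.39 (0.0227) and Irbp18 at 0.31 (0.0267). The call of Ets21C was lost without control replicate 1 or 2 or pool replicate 1 or 2 (adjusted p up to 0.0868), and that of Irbp18 on leaving out any 1 array but control replicate 2 (up to 0.108). Of 17 antimicrobial peptide genes 2 rose and 3 fell (2 and 5 adjusted over the list alone), and the list did not pass (median -0.11, camera adjusted p = 0.0633). Against the rise of Drs, Drsl4 stood at -0.63 (adjusted p = 0.011), the diptericin gene DptB at -0.45 (0.00447) and the defensin gene Def at -0.65 (0.0251). The call of Def was lost without control replicate 1 or 2 or pool replicate 3 (adjusted p up to 0.101). Of 5 Turandot genes, which encode stress-induced secreted peptides, 1 fell and 0 rose (the same adjusted over the list alone; camera adjusted p = 0.111, fry adjusted p = 0.0226): TotC fell by 0.78 on the log2 scale (adjusted p = 0.00548). Of 19 hemocyte genes 2 fell and 0 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.527), and both, PPO1 and PPO2, encode prophenoloxidases of crystal cells and stood at -0.36 (adjusted p = 0.00875 and 0.00827). Of 16 heat shock genes 1 rose and 0 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.683). This was Hsp70Bbb (0.44, adjusted p = 0.0405), which has near-identical copies and is uncertain, and whose call was lost on leaving out any 1 array but control replicate 2 (adjusted p up to 0.144) and with array weights (0.0577).

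Single glial and channel genes passed the test, at 4 of 36 and 4 of 37 measured, against 377 of 13346 genes in all, but neither list passed camera. Of 36 glial markers 2 rose and 2 fell (5 and 6 adjusted over the list alone; median -0.06, camera adjusted p = 0.334). The glial ensheathment gene wrapper fell by 0.47 on the log2 scale (adjusted p = 0.00299) and Obp44a, a binding protein gene also on the olfactory list, rose by 0.43 (0.00387). The glial sodium, potassium and calcium exchanger gene zyd stood at -0.42 (0.0149) and bdl at 0.26 (0.0459). Of 37 ion channel and pump genes 4 fell and 0 rose (the same adjusted over the list alone), although the list's median was 0.04 (camera adjusted p = 0.683). They were zyd, the inward rectifier genes Irk3 (-0.44, 0.0171) and Irk2 (-0.27, 0.0356), and the leak channel gene Ork1 (-0.32, 0.0334). Of 17 bang-sensitive seizure genes zyd alone fell and 0 rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.946). The calls of bdl, Irk2 and Ork1 were lost with any 1 array left out, that of zyd with any but control replicate 3 and that of Irk3 with any but control replicate 1, with adjusted p of up to 0.147, 0.134, 0.121, 0.0673 and 0.0773; bdl also lost it with arrays centred on the median (0.075). Of 28 neuropeptide genes 2 rose and 1 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.111). CCHa2 rose 1.51-fold (adjusted p = 0.00236), Nplp3 stood at 0.25 (0.0367) and NPF, the neuropeptide F gene, at -0.38 (0.0232). The call of Nplp3 was lost with any 1 array left out and that of NPF with any but control replicate 1 (adjusted p up to 0.134 and 0.0947); Nplp3 also lost it after quantile normalization (0.059) and with arrays centred on the median (0.0992). Of 13 immediate early activity genes 1 fell and 0 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.122): Cdc7 stood at -0.37 (0.0207), a call that was lost on leaving out any 1 array but control replicate 1 (adjusted p up to 0.0826).

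Camera called small shifts in 4 further lists, none of which passed with an estimated correlation. Of 22 phototransduction genes 18 were higher in the pool and 1 passed over all rows, with 0 falls (8 and 0 adjusted over the list alone), and the median was 0.10 (camera adjusted p = 8.91e-05; adjusted p = 0.353 with an estimated correlation). The 1 that passed was the photoreceptor adhesion gene chp (0.29, adjusted p = 0.0309), whose call was lost with any 1 array left out (adjusted p up to 0.119) and with each array centred on its median (0.0699). Of 30 ribosomal protein genes 29 were lower, with a median of -0.11 (camera adjusted p = 8.33e-06; adjusted p = 0.588 with an estimated correlation). Only 30 of the list's 82 members are named in the annotation used here. All 12 measured genes of the mitochondrial genome were higher, with a median of 0.11 (camera adjusted p = 0.00763; adjusted p = 0.937 with an estimated correlation), led by ND3 (0.45, adjusted p = 0.149) and ND4L (0.22, 0.247). That list's mean of 0.17 ranged from 0.08 to 0.25 with 1 array left out; the shift was lost without control replicate 3 (mean 0.08, adjusted p = 0.246) and without pool replicate 2 (0.12, 0.148), and the mean was highest without control replicate 1 (0.25). Of 32 olfactory binding and receptor genes 3 rose and 4 fell (3 and 10 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0163; adjusted p = 0.730 with an estimated correlation). Obp56e fell by 0.51 on the log2 scale (adjusted p = 0.00251), beside Obp99a at -0.86. The olfactory shift was lost without control replicate 1 (adjusted p = 0.109) and without pool replicate 3 (0.093). In all, camera called 7 of 37 lists, 5 upward and 2 downward. With an estimated correlation 0 passed the adjustment and 4 had an unadjusted p under 0.05, while fry called 6. Fry called the cuticle (adjusted p = 0.000122), muscle (0.000912), injury and JNK (0.00698) and phototransduction (0.00923) lists but not the ribosomal (0.0762), mitochondrial (0.410) or olfactory (0.120) lists. It also called 2 lists that camera did not, those of the genes named for the pooled lines (0.00698, upward) and the Turandot genes (0.0226, downward). The 1 called member of the pooled-line list is Ube3a, which 1 line overexpresses, so that call does not show a shared shift. Among lists that did not pass, the median, mean and camera direction also differed in sign for the P450, heat shock, bang-sensitive, glycolysis, female-biased, male-biased, clock and unfolded protein response lists, whose medians all lay within 0.04 of 0.

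**Figure D3:**
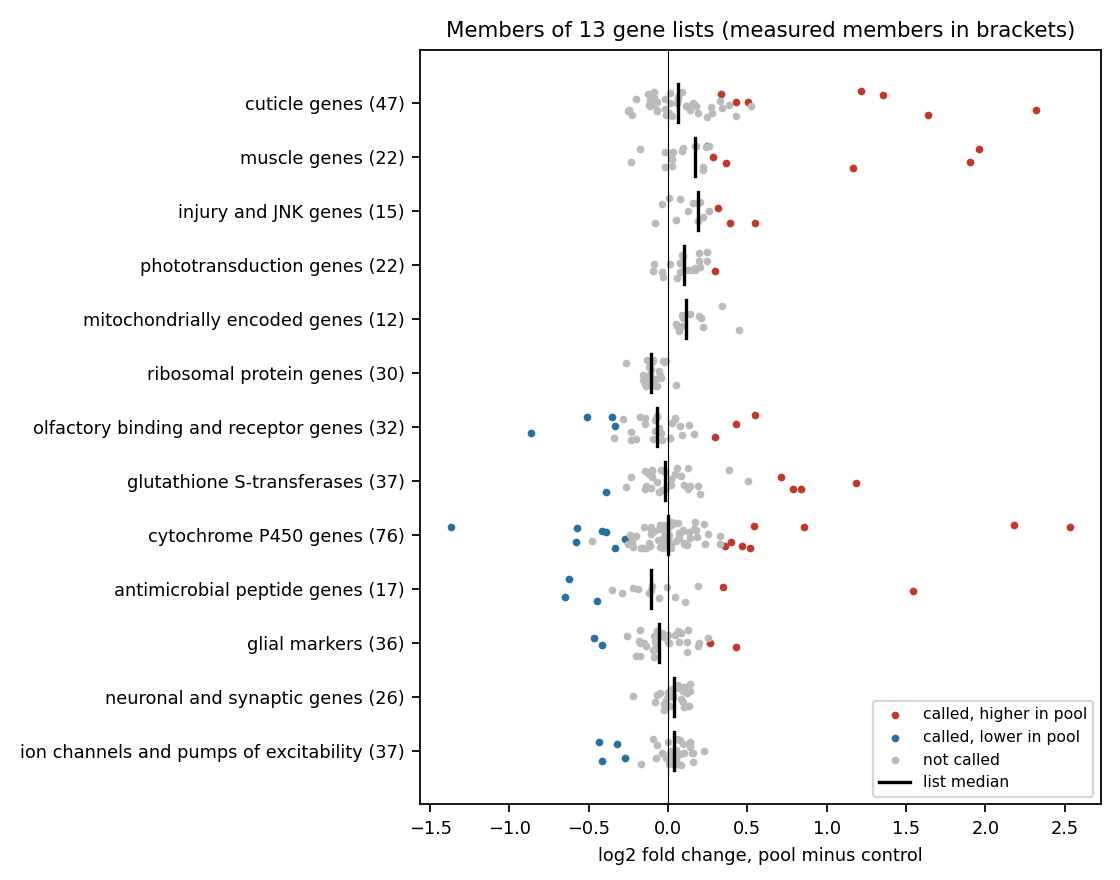
Log2 fold change of the pool over the control (x axis) for each measured member of 13 gene lists (rows), with members called higher in red, called lower in blue and not called in grey; the black bar is the list's median. The muscle median lies at 0.17 and the ribosomal median at -0.11, and the positions of points within a row carry no meaning beyond the x axis.

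Of the energy metabolism genes 1 of 58 oxidative phosphorylation genes and 3 of 28 insulin, fasting and fat metabolism genes passed the test, and neither list passed camera. Of 58 nuclear oxidative phosphorylation genes 1 rose and 0 fell (the same adjusted over the list alone; median 0.04, camera adjusted p = 0.0633). It was ND-B17, a complex I subunit gene (0.30, adjusted p = 0.0276), whose call was lost with any 1 array left out (adjusted p up to 0.110) and with each array centred on its median (0.0826). Of 28 insulin, fasting and fat metabolism genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.470). The gluconeogenesis gene Pepck1 fell by 0.49 on the log2 scale (adjusted p = 0.00828). The sugar-responsive transcription factor gene sug stood at -0.40 (0.0134) and the glucosidase gene tobi at 0.28 (0.0246). The call of sug was lost without control replicate 1 or pool replicate 1 or 3 (adjusted p up to 0.0585) and that of tobi with any 1 array left out (up to 0.103) and with each array centred on its median (0.0637). Of 17 clock genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.946); the 2 that fell, sug and Ugt35B1, are members of other lists too. The clock transcription factor gene vri stood at 0.40 (adjusted p = 0.0287), a call that was lost on leaving out any 1 array but control replicate 3 (adjusted p up to 0.107) and with each array centred on its median (0.0554). Of 9 male-biased genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.946). The dosage compensation RNA lncRNA:roX2 rose by 0.44 (adjusted p = 0.0051) and Cyp4d21 fell by 0.58 on the log2 scale (0.00112).

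In 12 of the 37 lists limma called 0 members over all rows. Besides the ribosomal and mitochondrial lists, whose members had an unadjusted p under 0.05 in 8 of 30 and 3 of 12 genes, these were lists of neuronal and synaptic genes (3 of 26 with an unadjusted p under 0.05; camera adjusted p = 0.305), immune recognition and signalling genes (6 of 26; 0.946), glycolysis genes (3 of 15; 0.888), female-biased genes (2 of 7; 0.888), transgene marker genes (1 of 14; 0.786), RNA interference genes (1 of 10; 0.616), glutamate and GABA cycle genes (1 of 18; 0.888), unfolded protein response genes (1 of 17; 0.946), septate and gap junction genes (4 of 22; 0.683) and proteasome genes (2 of 26; 0.470). Adjusted over the list alone, 2 glycolysis genes were higher and 1 lower, of the female-biased list msl-2 was higher and Yp3 lower, 1 immune recognition gene was lower, and 0 passed in the others. The members nearest the threshold were Tep4 (-0.24, adjusted p = 0.0533), a thioester protein gene, and the hexokinase gene Hex-C (0.25, 0.0515). The yolk protein gene Yp3 stood at -0.19 (0.0934) and msl-2 at 0.24 (0.0998); msl-2, though on that list, encodes a protein of male dosage compensation. The other member nearest the threshold was the synaptic active zone gene Rim, at -0.22 (0.0854).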

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

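The runs without the cuticle, muscle and digestive lists, and those of the muscle and cuticle lists without their largest risers, were chosen after seeing the data. Of the 473 called rows, 0 changed direction in any alternative that tested them. Most alternatives could not have changed it. In each called row all pool values lay on one side of all control values, so leaving out or weighting arrays could not reverse the difference. Only quantile normalization and centring on the median alter the values themselves. The count of called rows stayed within 1.5 times with quantile normalization (502), arrays centred on the median (468), the dimmest 25% dropped (557), rows with 1 symbol (453), array weights (540) and without the cuticle, muscle and digestive lists (452). With trend and robust settings limma called 861 rows, 476 higher and 385 lower, and an ordinary t-test called 196, 112 higher and 84 lower. Leaving out 1 array gave 218 to 312 rows, 124 to 174 higher and 88 to 147 lower; fewer arrays were tested, and no other cause was tested. Rows changed by at least 1.5-fold numbered 107 to 128 in these runs but 69 with the t-test, and 456 or 34 at a minimum of 1.2-fold or 2-fold, which follows from the minimum itself. The cause of the other differences was not tested.

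No clear pairing by replicate number was seen. Deviations of arrays with the same number correlated at -0.01, -0.00 and 0.09, and control replicate 1 correlated best with pool replicate 2 (0.08). The highest correlation of all, 0.09, was that of control replicate 3 with pool replicate 3, so a batch shared by number is not excluded. With the replicate block limma called 312 rows (190 higher, 122 lower), 288 of them among the 473. With an estimated correlation 0 of 37 lists passed, against 7 with the preset one; fry called 6, and 6 to 9 were called when 1 array was left out. Without Act88F, fln and TpnC4 the muscle list's mean fell from 0.32 to 0.11; it still passed camera (adjusted p = 0.00208), with an unadjusted estimated-correlation p of 0.0548. Of the 77 called named genes, 54 kept the call with each array left out, 34 lost it with the ordinary t-test, 19 with the replicate block, 7 with arrays centred on the median, and 1 each with quantile normalization and with array weights. In the 12 lists with 0 members called by limma the ordinary t-test called 1 gene, a female-biased one. The calls lost with the ordinary t-test included GstD5 (adjusted p = 0.122), GstE7 (0.119), Drsl4 (0.116), Drs (0.0925), TotC (0.0925), CG10912 (0.0882), Gadd45 (0.0785), Pepck1 (0.0733), Spn47C (0.0664), LysP (0.0587), Ugt301D1 (0.0583), Cpr97Eb (0.0565) and Obp99b (0.056). The difference of htt, which did not pass, ranged from -0.052 to 0.042 with 1 array left out and changed sign without control replicate 1 (0.042) and without pool replicate 2 (0.0071). Genes named by the rule have 1 row each, so the mean over rows gave no value for them. The signal of dim rows over background is not given in the sources used here.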

Other observations

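All gene families of this paragraph and the next were chosen after the values were seen, so their counts describe these data and are not independent tests. Of 5 chitin deacetylase genes 4 rose, serp (log2 fold change 0.86), Cda4 (0.77), verm (0.65) and Cda5 (0.42), with limma adjusted p of 0.00103, 0.00456, 0.00828 and 0.0109. Of 4 Vajk genes 2 rose, Vajk3 and Vajk2 (1.33, adjusted p = 0.000236), and of 8 obstructor genes 2 rose, while 1 of 10 chitinase genes rose and 0 of 25 Tweedle genes were called. The retrotransposon-derived capsid genes Arc1 and Arc2 both rose: Arc1, already bright in the control at 12.10, rose 2.12-fold (adjusted p = 3.52e-05) and Arc2 1.43-fold (0.00371).

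Of 21 DNA damage and replication genes 5 rose and 0 fell, among them the replication clamp gene PCNA (0.79, adjusted p = 0.00531) and RPA1 (0.39, 0.0155). Gadd45 and Irbp18, also among the 5, are called members of the injury and JNK list too. The call of Irbp18 was lost on leaving out any 1 array but control replicate 2. Cdc7, which limma called lower (-0.37, adjusted p = 0.0207), was not among the 21, so the count of 0 falls depends on the genes chosen. Of 23 visual system genes outside the phototransduction list 7 rose and 0 fell, including Pph13 (0.46, 0.0084), ort (0.43, 0.00521), which encodes a histamine receptor of the neurons that photoreceptors contact, and the photoreceptor gene Cpn (0.38, 0.00733). In folate and glycine metabolism, Gnmt, the glycine N-methyltransferase gene, rose 2.02-fold (adjusted p = 0.000125) and Nmdmc rose while CG8665 fell, out of 11 genes measured. Of 214 small nucleolar RNA genes 4 rose and 8 fell.

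The tests of this and the following paragraphs were chosen after the result was seen, except the splits of the arrays and the test of the homeotic and trunk genes. Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 473 rows, 125 rows at 1.5-fold and 7 lists; the highest other split gave 0, 0 and 5, so that 1 split of 10, the real one, reached each of these 3 values.

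Of the cuticle genes 7 of 47 rose, of the muscle genes 6 of 22 and of the digestive enzyme genes 5 of 42; camera called the first pair of lists, but neither passed with an estimated correlation (adjusted p = 0.160 and 0.143), and the cuticle call ended without its 4 largest risers (0.113). A candidate explanation is that more thoracic tissue came along when heads were removed. The 19 muscle genes other than Act88F, fln and TpnC4 also lay above the rest, as more thoracic tissue would give (mean 0.11, standard error 0.036, 15 higher; camera p = 0.000281, p = 0.0548 with an estimated correlation, and p = 0.1 in an exact two-sided permutation of the arrays, the smallest that 6 arrays allow), though these went both ways, from TpnC73F at 0.37 to Msp300 at -0.23, with the bright Mlc2 (12.73 in the pool) and Mlc1 (12.10) at 0.10 and 0.25. The homeotic and trunk genes, 7 measured and 1 of them, Sur-8, listed in error, had a mean of 0.07 (standard error 0.039). They did not decide (camera p = 0.209 and p = 0.2 in the exact permutation). Antp, vg and tsh read 4.43, 4.41 and 4.72 in the control, near the limit of the dimmest 25% of rows (4.23). This limits what the set could show. Muscle of the head itself, a difference in age after eclosion and an effect of the altered glia stay open and were not tested.

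The falls bear on how many of the 7 lines share a change. If 1 line lost a transcript entirely and the others kept the control level, the pool would sit at 85.7% of the control, a log2 change of -0.22. In a one-sided moderated test of all 16322 rows against that limit, 30 rows lay beyond it after adjustment, which argues against a loss in only 1 of the 7 pooled lines for those 30 and leaves it open for the other 173 called falls. The rises carry no such limit, because 1 line could in principle give all of a rise. That line would need to stand at 7.73 times the control for Ube3a, which 1 line overexpresses. It would need 21.2 times for Act88F and 34.5 times for Cyp6a2. How many lines share a rise is therefore not known. That the single control genotype is itself the odd one stays open, because genetic background and group cannot be separated in this design.

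The male-specific dosage compensation RNAs roX1 and roX2 were higher in the pool, lncRNA:roX1 by 0.26 (adjusted p = 0.0356) and lncRNA:roX2 by 0.44. A higher share of males in the pool samples would raise male-biased transcripts and lower female-biased ones. Of the 7 other male-biased genes measured, 2 were called lower (Cyp4d21 and Obp56e), against that explanation, and 1 higher (tobi). The call of tobi was lost with any 1 array left out (limma adjusted p up to 0.103), while the 2 lower calls were kept. This count covers the fixed list only and leaves out any male-biased gene outside it. The yolk protein gene Yp3 (-0.19, adjusted p = 0.0934) and msl-2 (0.24, 0.0998), whose protein acts in males, were not called but lay on the side that more males would give. The 7 genes of the female-biased list did not move together, with 3 higher, 4 lower and a median of -0.00 (camera adjusted p = 0.888). That list holds msl-2, so more males need not move it as a whole, and its median and camera test do not bear on the question. The values do not decide, the sex of the flies is not given in the labels, and an effect of the altered glia was not tested.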
